A study of Oryza sativa with 19 samples.

How the data were processed

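Total RNA was measured on 19 single-colour Agilent rice arrays, in ovules of 6 developmental stages with 3 replicates each for E1 to E5 and 4 for E6. Per the labels' protocols, pistils of field-grown Nipponbare plants were fixed in acetone and embedded in paraffin. Ovules were cut by laser from sections 10 µm thick, RNA was taken with the PicoPure kit from 50 to 150 pieces per sample, and Cy3-labelled cRNA was made with the Quick Amp kit, with cDNA synthesis extended to 6 h. Per the file headers, the arrays lie on 6 slides scanned in 4 scans. Slide 1 holds replicate 1 and slide 2 replicate 2 of E1, E2, E4 and E5. Slide 3 holds replicate 3 of E1 and E4, slide 4 replicate 3 of E2, slide 5 the E3 arrays and E5 replicate 3, and slide 6 the E6 arrays. Scan 1 covers slides 1 to 3, and slides 4, 5 and 6 were each scanned on a date of their own. On slides 1 to 3 the position on the slide follows the stage.

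The scanner files hold a processed signal intensity per spot, which the authors' Agilent Feature Extraction software (9.5.3.1) made with background subtraction and detrending within the array, substitute values for dim spots and no scaling between arrays, per the file headers. The deposited flags (other columns of these files) mark spots as well above background, saturated or unlike their neighbours, per the file headers. The deposited values of the whole series are linear intensities that equal the processed signal times 1 constant per array, with a 75th percentile near 10 on every array. Their scale, centring and direction are therefore known: linear, not centred, and higher for more signal. Column medians were 1.78, 1.87 and 1.99 for E1 replicates 1 to 3, 2.12, 2.07 and 2.13 for E2, 1.60, 1.56 and 1.49 for E3, 1.79, 1.71 and 1.84 for E4, 1.70, 1.81 and 1.66 for E5, and 1.82, 1.65, 1.66 and 1.68 for E6 replicates 1 to 4.

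Of 45151 spots per array, control spots were left out, and spots with an outlier flag (17 to 46 per array) were set missing on that array. Processed signals were put on the log2 scale, spots of a probe were averaged, and the 75th percentile of the array was subtracted. Of several probes of a gene (7796 genes) the probe with the highest mean signal over all arrays stood for the gene. A feature was tested if its probe was well above background on all arrays of at least 1 stage. This gave 21599 features, called genes here, of which 21399 carry a locus of the Rice Annotation Project and 200 carry none. Other probes of called genes gave an opposite change that also passed in 2, 84, 8, 0, 5, 87 and 191 cases in the comparisons of E1 to E2, E2 to E3, E3 to E4, E4 to E5, E5 to E6, E2 to E4 and E1 to E5. Gene positions are not given, since the gene table held for the genome matched 0 of the 21399 loci.

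Stage means were fitted to all 19 arrays with limma 3.58.1 in R 4.3.3, without covariates, and variances were moderated with eBayes. A moderated F-test compared the 6 stages, and moderated contrasts compared adjacent stages, E2 with E4 and E1 with E5. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison and called at an adjusted p under 0.05. With 3 arrays against 3, chance alone puts all values of a gene in 1 group above those of the other in 10% of genes. Slide was not in the model because E6 has a slide of its own and E3 shares its slide with 1 array of E5. Slide as a fixed or a random block (consensus correlation 0.204) was an alternative.

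27 gene lists were written as symbols with loci and as word patterns for the array's gene descriptions: meiosis, recombination and repair, DNA replication, mitotic cyclins and spindle, histones, MADS-box factors, meristem and organ polarity regulators, B3 domain factors, egg cell and gamete genes, cysteine-rich secreted peptides, small RNA pathway, DNA methylation and polycomb, auxin, gibberellin, cytokinin, cell wall, proteases, ribosomal proteins, heat shock and chaperones, proteasome, starch and sucrose, metallothionein with ubiquitin and senescence genes, and markers of photosynthetic tissue, tapetum and anther wall, pollen, seed storage and vascular tissue. The symbol and locus pairs (77, over 76 loci) were written from memory. Of these loci 3 are not on the array, and the array's description of 10 names no function. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 26 lists and 7 comparisons (182 tests). The egg cell list has too few members (3) for a test. With the preset correlation 45 shifts passed (11 to 48 in other splits), and with an estimated one 0 of them did. The rotation test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, passed in 84 tests, and in 153 for a change in either direction.

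Named genes follow a rule. Among changed genes with no overlap between the arrays of both stages, well above background on every array of the higher stage and with an informative description, it takes the 10 largest rises and the 10 largest falls (5 and 5 for E2 to E4). It adds up to 4 changed members of each list with the largest change. Where the lists named more genes than the text could hold, those printed were chosen after their values were seen, and some results that the rule names are not reported here. Gene names are the array's descriptions, and symbols from the lists were added from memory. The comparisons, tests, lists, naming rule and most other ways of processing were fixed before the data were examined.

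Other processing fixed beforehand was normexp background correction with an offset of 50, quantile normalization, the series table, other treatments of dim probes, outlier spots and several probes per gene, eBayes with trend and robust settings, array weights, slide and replicate blocks, fits on the compared groups alone, a 2-fold minimum, and leaving out each array in turn. Scaling on probes well above background on all arrays, chosen after the data were seen, used 13536 probes. On simulated data, 84% to 100% of 50 genes shifted by a log2 of 3 were called. Of those shifted by 1, 18% to 52% were. False calls were 4 to 13 among 21349 genes, not an error rate for real arrays. Tables were read with data.table (1.17.8) and prepared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.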

Results

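The series holds 19 Agilent arrays of rice ovules cut by laser from paraffin sections. There are 6 stages, with 3 arrays each from E1 to E5 and 4 in E6. Ovules were not split by cell type, so changes in germ cells, other tissue or tissue proportions cannot be told apart. By the sample labels, E1 spans the time before meiosis up to leptotene, E2 zygotene and pachytene, E3 diplotene to the tetrad, E4 the mononuclear female gametophyte, E5 its growth from 2 to 8 nuclei, and E6 the mature ovule. The 75th percentile of the processed signal was 16.8 to 45.7 units on the 6 arrays of E1 and E2 and 240 to 799 on the 13 later arrays. Spots well above background made up 35.3% to 53.4% and 64.6% to 81.6%, respectively. No spot was saturated. A gene is called measured in a stage where its probe was well above background on every array of that stage. Changes are log2 differences with their SE from limma, over 21599 genes, and a gene counts as changed at an adjusted p under 0.05. Nothing states that the biological replicates of the series design came from separate plants. The p-values measure only the spread between these samples, which may be technical and is pooled over all stages. The number of arrays limits the precision.

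**Figure D1:**
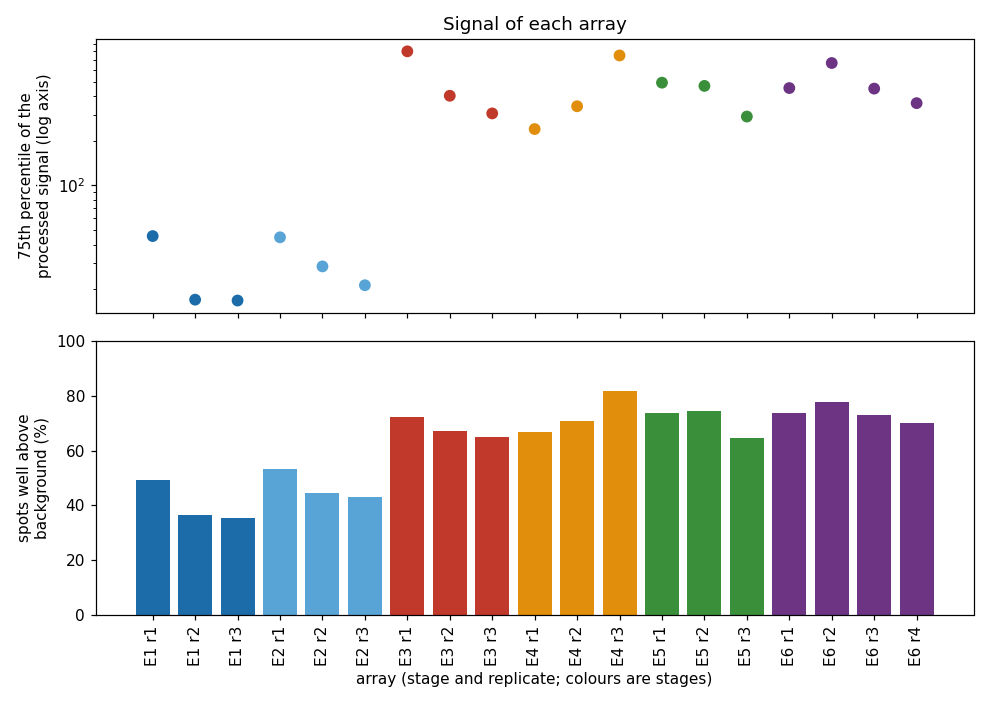
Upper panel: the 75th percentile of the processed signal of each of the 19 arrays (scanner units, log axis). Lower panel: the share of its spots well above background (percent), with colours for stages and r for the replicate.

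Of the 21599 genes, 16616 (76.9%) differed among the 6 stages by the moderated F-test. Among the 9292 genes measured on all 19 arrays, 7101 differed. Among those, the highest mean lay in E1 for 1696, in E2 for 985, in E3 for 1706, in E4 for 491, in E5 for 479 and in E6 for 1744. The first principal component over 13536 probes held 60.5% of the variance and set the arrays of E1 and E2 (61.1 to 97.4) apart from all later arrays (-75.8 to -2.04). The second held 18.8% and set the E3 arrays (67.6 to 71.3) apart from the other stages, with E4 replicate 2 at 32.1 and E5 replicate 3 at 12.

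The comparison of E1 to E2 follows the ovule into meiotic prophase. The argonaute MEL1 (Os03g0800200), which germ cells of rice need for early meiosis, fell by 3.39 ± 0.33 on the log2 scale (SE, n = 3 arrays per stage, adjusted p = 4.44e-05). Another argonaute gene, Os07g0188000, rose by 2.22 ± 0.27 (adjusted p = 0.000232). BABY BOOM (Os03g0232200), an AP2-family regulator of embryo growth, fell by 3.40 ± 0.80 (adjusted p = 0.0172) and was measured on 1 of 3 E2 arrays, and BABY BOOM1 (Os03g0770700) fell by 1.64 ± 0.34 (adjusted p = 0.00813). PAIR2 (Os09g0506800), a protein of the meiotic chromosome axis, rose by 0.86 ± 0.19 (adjusted p = 0.0116). MSH5 (Os05g0498300), which acts in crossover formation, was below background on all E1 arrays and rose at least 1.74-fold (adjusted p = 0.0119). For genes below background in the lower stage, bounds compare stage means, with signals there raised to at least the array's lowest well above background. Such bounds allow for neither slide nor spread, and the p-value beside one tests the unbounded change.

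Among the largest rises, a GDSL lipolytic enzyme (Os04g0507700) rose at least 22.2-fold (adjusted p = 1.43e-08), an alpha-galactosidase (Os07g0452100) at least 7.18-fold (adjusted p = 8.37e-05) and a fatty acyl coenzyme A reductase (Os08g0557800) at least 3.76-fold (adjusted p = 8.37e-05), each below background on all 3 E1 arrays. A lipid transfer protein (Os01g0822900) rose by 3.44 ± 0.36 (adjusted p = 7.27e-05). The alpha-expansin OsEXPA4 (Os05g0477600), of a family that loosens cell walls, rose by 3.28 ± 0.54 (adjusted p = 0.00193) and was measured on 1 of 3 E1 arrays. The MADS-box gene OsMADS29 (Os02g0170300) rose (adjusted p = 3.04e-06), without a bound, since its probe was below background on the E1 arrays while another probe of the gene was not. OsMADS21 (Os01g0886200), of the AGAMOUS group, rose by 1.20 ± 0.25 (adjusted p = 0.00876). Among the falls, a SUMO conjugating enzyme (Os04g0580400) fell by 2.95 ± 0.37 (adjusted p = 0.000277), measured on 1 of 3 E2 arrays. A YABBY family gene (Os02g0643200) fell by 2.70 ± 0.58 (adjusted p = 0.0108), an AUX/IAA gene (Os01g0190300) fell by 2.41 ± 0.48 (adjusted p = 0.00661) and a beta-amylase (Os10g0565200) by 2.16 ± 0.59 (adjusted p = 0.0352), each measured on 2 of 3 E2 arrays. Of the 10 largest rises and the 10 largest falls, 5 and 1 were below background in the lower stage.

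By list, 3 auxin genes rose, 9 fell and 60 did not pass (3 and 11 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.0106, adjusted p = 0.290 with an estimated correlation). Of 15 meristem and organ polarity regulators 1 rose, 3 fell and 11 did not pass (1 and 3 adjusted over the list alone), with a median of -0.73 (adjusted p = 0.0414, adjusted p = 0.349 with an estimated correlation). Of 244 ribosomal protein genes 4 rose, 10 fell and 230 did not pass (2 and 5 adjusted over the list alone), with a median of -0.30 (adjusted p = 3.47e-08, adjusted p = 0.720 with an estimated correlation). Of 54 proteasome genes 1 rose and none fell (0 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0152, adjusted p = 0.776 with an estimated correlation). On slide 1 and slide 2 alone the medians were -0.19 and -0.55 for auxin, -1.20 and -0.67 for the meristem list, -0.22 and -0.23 for ribosomal proteins and -0.23 and -0.14 for the proteasome. Of 27 meiosis genes 3 rose, 1 fell and 23 did not pass (6 and 1 adjusted over the list alone, adjusted p = 0.304), and the gene that fell is MEL1. Of 28 MADS-box factors 4 rose, 3 fell and 21 did not pass (4 and 3 adjusted over the list alone), and the median of -0.07 differs in sign from the mean of 0.12 and from the test (adjusted p = 0.441). The proteasome shift had an adjusted p of 0.0670 with slide as a fixed block.

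From E1 to E2 1830 genes changed, 1124 higher and 706 lower. Among the 9452 genes measured in both stages 640 changed, 266 higher and 374 lower. The share of higher calls, 61.4%, was 73.7% with scaling on probes measured everywhere and 90% after normexp. With slide as a fixed block 413 genes passed, and among the 17 genes named here PAIR2, MSH5, OsMADS21, BABY BOOM1, the beta-amylase, OsEXPA4 and the YABBY gene did not (adjusted p from 0.0508 to 0.209). Their changes in that fit were 0.80, 0.74, 0.93, -1.55, -2.18, 3.28 and -2.35 in this order. Fitted on E1 and E2 alone, limma called 0 genes (3367 at an unadjusted p under 0.05), so the calls rest on the spread pooled over all stages. After normexp 30 genes passed. The normexp correction shrank the list medians to -0.10 for auxin, which still passed, and to -0.10 for the meristem list (adjusted p = 0.219), -0.02 for the proteasome (adjusted p = 0.921) and -0.06 for ribosomal proteins (adjusted p = 0.171). Under quantile normalization the medians were -0.12 for the proteasome (adjusted p = 0.0921) and -0.16 for ribosomal proteins. The proteasome median was -0.13 with scaling on probes measured everywhere, and that of auxin -0.58 without E1 replicate 1. The count was 1020 without E2 replicate 1 and 1218 without E2 replicate 2. BABY BOOM no longer passed without E2 replicate 2 (adjusted p = 0.0569), and the beta-amylase when any 1 of 4 arrays was left out (adjusted p up to 0.119, without E2 replicate 1). The meristem shift was not called without E1 replicate 1 (adjusted p = 0.180), E2 replicate 1 (0.0725), E2 replicate 3 (0.145), E4 replicate 1 (0.0580) or E4 replicate 2 (0.0586). Nor was the proteasome shift called without E1 replicate 1 (adjusted p = 0.0840) or E2 replicate 3 (0.0703).

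**Figure D2:**
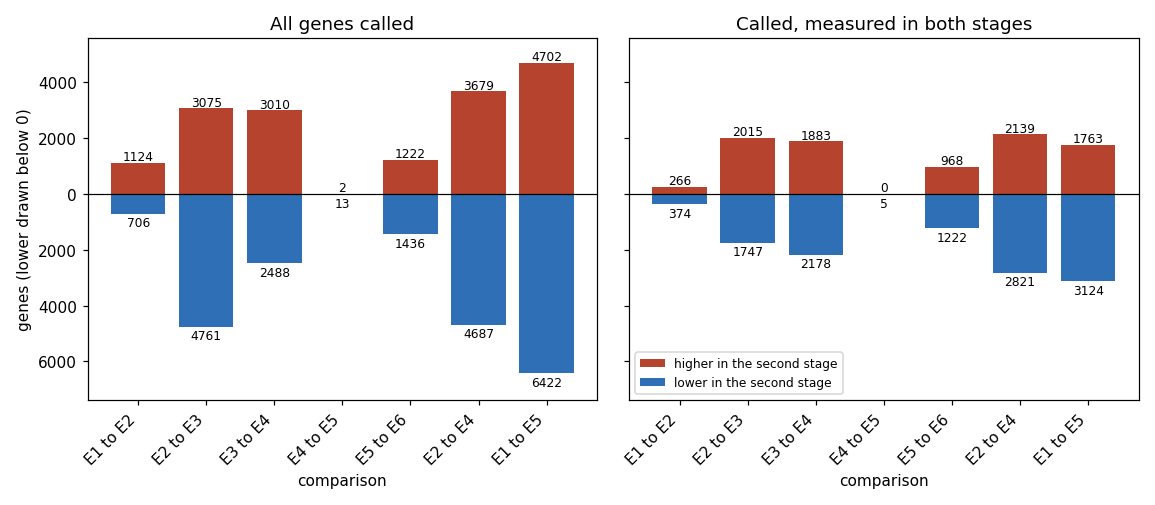
Number of genes higher (red, above 0) and lower (blue, below 0) in the second stage of each comparison at an adjusted p under 0.05, for all 21599 genes (left) and for genes well above background on every array of both stages (right).

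The comparison of E2 to E3 covers the end of meiosis. Another gene described as BABY BOOM1 (Os04g0653600) fell by 4.23 ± 0.28 (SE, n = 3 arrays per stage, adjusted p = 8.07e-07). A gibberellin 2-beta-dioxygenase (Os05g0560900), an enzyme that inactivates the hormone, fell by 3.84 ± 0.59 (adjusted p = 9.97e-05), and a gibberellin 20-oxidase (Os01g0883800), an enzyme of its synthesis, fell by 3.37 ± 0.53 (adjusted p = 0.000119). The recombination gene XRCC3 (Os02g0562100) fell by 3.71 ± 0.58 (adjusted p = 0.000119), while RAD51A1 (Os11g0615800), the strand exchange protein, rose by 0.93 ± 0.32 (adjusted p = 0.0336). The argonaute Os07g0188000 rose by 1.66 ± 0.27 (adjusted p = 0.000188). The polycomb gene EZ1 (Os03g0307800) was below background in E2 and rose at least 1.27-fold (adjusted p = 0.000830), but changed by -1.14 after the normexp background correction (adjusted p = 6.03e-06).

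The fatty acyl coenzyme A reductase Os08g0557800 rose by 3.12 ± 0.35 (adjusted p = 8.01e-06). A sucrose transporter (Os02g0576600) rose by 2.91 ± 0.30 (adjusted p = 5.10e-06), a heavy metal domain gene (Os07g0671400) by 3.96 ± 0.35 (adjusted p = 3.39e-06) and an NADPH HC toxin reductase (Os06g0651100) by 3.69 ± 0.48 (adjusted p = 2.57e-05), each measured on 1 of 3 E2 arrays. An esterase (Os01g0859200), below background in E2, rose at least 4.19-fold (adjusted p = 4.33e-06) but changed by -0.08 after the normexp correction. Large falls ended below background in E3: a terpenoid cyclase domain gene (Os05g0237700) fell at least 293-fold (adjusted p = 2.72e-05), a NUDIX hydrolase (Os11g0531700) at least 304-fold (adjusted p = 2.01e-06), farnesyl diphosphate synthase (Os04g0657100) at least 272-fold (adjusted p = 3.99e-06) and a protein kinase (Os06g0654500) at least 247-fold (adjusted p = 6.76e-06). The alpha-expansin OsEXPA14 (Os02g0267700), also below background in E3, fell at least 197-fold (adjusted p = 5.48e-06). An En/Spm-like transposon gene (Os12g0422700) fell by 7.98 ± 1.52 (adjusted p = 0.000692), measured on 1 of 3 E3 arrays. Histone H2B.1 (Os01g0149400), a core chromatin protein, fell by 2.89 ± 0.32 (adjusted p = 6.83e-06). Of the 50 histone genes 3 rose and 3 fell (2 and 3 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.267), and 1.45 after normexp (adjusted p = 5.23e-08). Of the 10 largest rises and the 10 largest falls, 5 and 8 were below background in the lower stage.

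Markers of photosynthetic tissue moved with this step: of 68 genes 5 rose, 44 fell and 19 did not pass (5 and 44 adjusted over the list alone), with a median of -1.51 (adjusted p = 5.04e-08, adjusted p = 0.263 with an estimated correlation). Among them a RuBisCO large chain gene (Os05g0427800) fell by 5.24 ± 0.39 (adjusted p = 1.43e-06) and a chlorophyll a-binding protein (Os10g0356500) fell by 5.36 ± 0.61 (adjusted p = 8.74e-06), each measured on 1 of 3 E3 arrays. Of the 18 measured in both stages 4 rose and 9 fell. Of 15 meristem and organ polarity regulators 1 rose, 10 fell and 4 did not pass (1 and 10 adjusted over the list alone), with a median of -1.82 (adjusted p = 0.000945, adjusted p = 0.163 with an estimated correlation). Of 11 gibberellin genes 7 fell and 4 did not pass (0 and 7 adjusted over the list alone), with a median of -2.54 (adjusted p = 0.0296, adjusted p = 0.365 with an estimated correlation). Of 72 auxin genes 6 rose, 29 fell and 37 did not pass (7 and 30 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.0303, adjusted p = 0.349 with an estimated correlation) that turned to 0.08 under quantile normalization. Of 35 seed storage genes 4 rose, 14 fell and 17 did not pass (4 and 15 adjusted over the list alone, adjusted p = 0.0811). Prolamin 7 (Os05g0329400) fell by 6.60 ± 0.84 (adjusted p = 2.04e-05).

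Ribosomal protein genes rose more often than they fell, 43 against 7 of 244 with 194 not passing (31 and 7 adjusted over the list alone), with a median of 0.25 (adjusted p = 1.38e-05, adjusted p = 0.747 with an estimated correlation). Of 56 mitotic cyclin and spindle genes 9 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.0296, adjusted p = 0.720 with an estimated correlation). Of 32 DNA replication genes 7 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.0296, adjusted p = 0.723 with an estimated correlation) that turned to -0.09 with slide as a fixed block (adjusted p = 0.555) and was not called with a random block (adjusted p = 0.115). Of 54 proteasome genes 1 rose and none fell (0 adjusted over the list alone), with a median of 0.21 (adjusted p = 0.0392, adjusted p = 0.797 with an estimated correlation). The proteasome shift was not called without E2 replicate 3 (adjusted p = 0.121) or E3 replicate 3 (0.123). Nor was the spindle shift called without E3 replicate 3 (adjusted p = 0.0502). Quantile normalization ended the shifts of the proteasome (adjusted p = 0.812), the spindle list (adjusted p = 0.42), DNA replication (adjusted p = 0.228) and auxin (adjusted p = 0.205). After normexp those of the meristem list (adjusted p = 0.213), auxin (adjusted p = 0.241) and gibberellin (adjusted p = 0.553) did not pass. Under quantile normalization the medians were -0.24 for photosynthetic markers, -0.48 for the meristem list and -1.18 for gibberellin. After normexp they were -2.23, -2.30 and -2.31, with -1.66 for auxin, 0.19 for DNA replication, 1.34 for ribosomal proteins and 1.08 for the proteasome. The proteasome had 0.38 with slide as a fixed block and 0.13 with scaling on probes measured everywhere.

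From E2 to E3 7836 genes changed, 3075 higher and 4761 lower. Among the 11962 genes measured in both stages 3762 changed, 2015 higher and 1747 lower. The share of higher calls, 39.2%, was 61.6% under quantile normalization, which moved the median of all genes by 0.16, while normexp moved it by -0.21. No slide holds both E2 and E3, and with slide as a fixed block 1261 genes passed. Changes in that fit, several below the bounds, were -4.94 for the terpenoid cyclase gene, -4.70 for the protein kinase, -5.50 for OsEXPA14, -7.05 for the NUDIX hydrolase, -7.42 for farnesyl diphosphate synthase and -2.45 for the transposon gene (adjusted p = 0.721). They were -3.75 for prolamin 7, -2.19 for the 2-beta-dioxygenase, -2.05 for the 20-oxidase and 0.54 for RAD51A1. Of the 22 genes named here 9 passed in it: the argonaute, H2B.1, BABY BOOM1, RuBisCO, the heavy metal gene, the esterase, the sucrose transporter, the NUDIX hydrolase and the protein kinase. RAD51A1 lost its call without any 1 of 5 arrays (adjusted p up to 0.0935, without E2 replicate 2).

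The comparison of E3 to E4 runs from the tetrad to the mononuclear female gametophyte. The gene described as ANT, an AINTEGUMENTA-like factor (Os07g0124700), fell by 4.94 ± 0.33 (SE, n = 3 arrays per stage, adjusted p = 2.65e-07). A thaumatin family gene (Os12g0568900), of a family of pathogenesis-related proteins, was below background in E3 and rose at least 543-fold in E4 (adjusted p = 3.11e-06). The DNA methyltransferase MET1-1 (Os03g0798300), which maintains CG methylation, fell by 1.76 ± 0.38 (adjusted p = 0.00442) and the chromomethylase CMT3A (Os10g0104900) by 1.58 ± 0.40 (adjusted p = 0.0109). MET1-2 (Os07g0182900) fell by 1.08 ± 0.33 (adjusted p = 0.0275). RAD51A1 (Os11g0615800) fell by 1.78 ± 0.32 (adjusted p = 0.00135). The receptor kinase MSP1 (Os01g0917500), which limits the number of cells entering meiosis, fell by 1.09 ± 0.19 (adjusted p = 0.000856), and PAIR3 (Os10g0405500), a chromosome axis protein of meiosis, by 0.98 ± 0.32 (adjusted p = 0.0345).

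**Figure D3:**
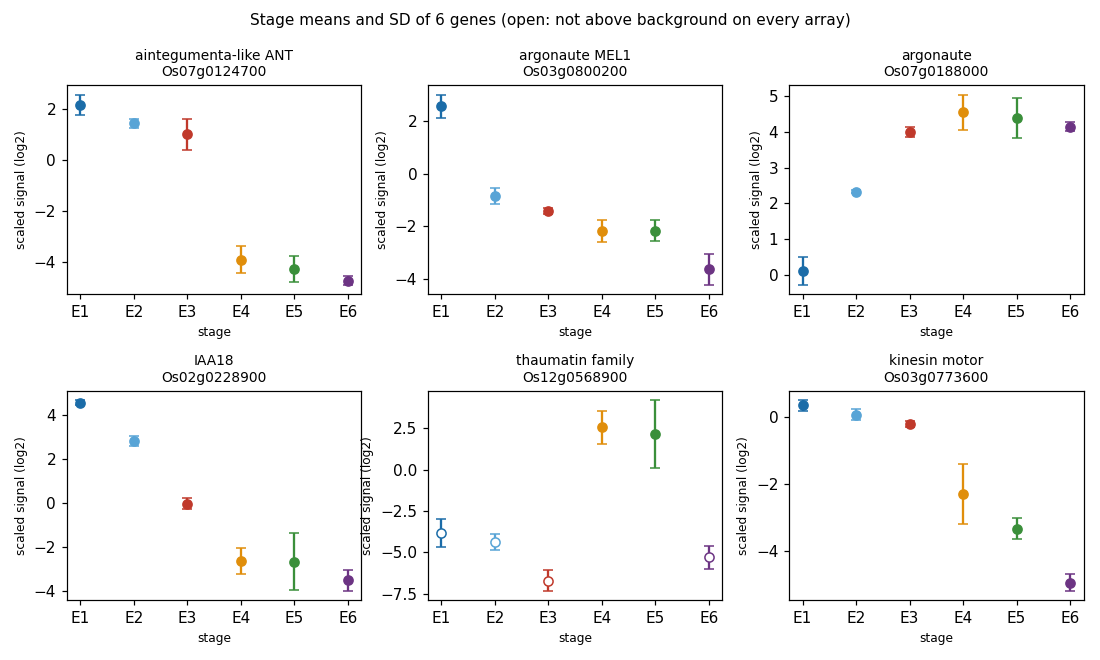
Mean scaled signal (log2) of 6 genes in each stage, with SD over 3 arrays (4 in E6), each panel on its own scale, with open circles where the probe was not well above background on every array.

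Among the largest rises, a BURP domain gene (Os02g0288600) rose by 7.44 ± 0.68 (adjusted p = 5.87e-06). A pectin methylesterase inhibitor family gene (Os04g0587200) rose at least 138-fold (adjusted p = 1.41e-05) and arginine decarboxylase (Os04g0107600), an enzyme of polyamine synthesis, at least 85.4-fold (adjusted p = 6.45e-07). An exostosin family gene (Os07g0188700) rose at least 75.5-fold (adjusted p = 2.87e-07). All 3 were below background in E3. An NAD-binding site gene (Os09g0498500) rose by 6.10 ± 0.27 (adjusted p = 3.43e-09), measured on 2 of 3 E3 arrays. A gibberellin MYB factor (Os03g0578900) rose by 6.00 ± 0.74 (adjusted p = 6.65e-05), measured on 1 of 3 E3 arrays. Among the falls, a glutathione S-transferase (Os01g0371500) fell at least 83.0-fold to below background (adjusted p = 2.37e-07). A lipid transfer or amylase inhibitor family gene (Os03g0663900) fell by 6.06 ± 0.31 (adjusted p = 1.51e-08), the MADS-box gene OsMADS16 (Os06g0712700) by 3.83 ± 0.79 (adjusted p = 0.00324) and a small heat shock protein (Os01g0135900) by 4.59 ± 0.84 (adjusted p = 0.00148), each measured on 2 of 3 E4 arrays. A Bowman-Birk proteinase inhibitor (Os01g0127600) fell by 5.01 ± 0.75 (adjusted p = 0.000338) and OsMADS34 (Os03g0753100) fell by 3.61 ± 0.33 (adjusted p = 5.34e-06). Of the 10 largest rises and the 10 largest falls, 6 and 4 were below background in the lower stage.

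Of 50 histone genes 2 rose, 28 fell and 20 did not pass (2 and 37 adjusted over the list alone), with a median of -1.18 (adjusted p = 1.05e-09, adjusted p = 0.663 with an estimated correlation). A histone H3 gene (Os05g0438700) fell by 2.04 ± 0.52 (adjusted p = 0.0105) and a histone H2A gene (Os05g0113900) by 1.97 ± 0.51 (adjusted p = 0.0116). E4 replicate 2 showed no such fall: its histone mean was 0.75, against 0.74 to 0.92 on the E3 arrays and -0.89 and -0.14 on the other E4 arrays. Its means for the proteasome (0.30) and ribosomal proteins (0.20) were also near those of E3 (0.32 to 0.46 and 0.22 to 0.30). Of 56 mitotic cyclin and spindle genes 3 rose, 25 fell and 28 did not pass (3 and 29 adjusted over the list alone), with a median of -0.60 (adjusted p = 2.40e-07, adjusted p = 0.401 with an estimated correlation). A kinesin motor gene (Os03g0773600) fell by 2.09 ± 0.31 (adjusted p = 0.000340). Of 244 ribosomal protein genes 3 rose, 79 fell and 162 did not pass (3 and 94 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.73e-13, adjusted p = 0.663 with an estimated correlation). L44 (Os07g0450000) fell by 2.20 ± 0.26 (adjusted p = 4.57e-05). Of 54 proteasome genes 1 rose, 24 fell and 29 did not pass (1 and 33 adjusted over the list alone), with a median of -0.51 (adjusted p = 2.79e-08, adjusted p = 0.662 with an estimated correlation). Subunit beta type 1 (Os08g0529100) fell by 2.79 ± 0.40 (adjusted p = 0.000218). Of 32 DNA replication genes 3 fell and 29 did not pass (0 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.00276, adjusted p = 0.720 with an estimated correlation) that turned to 0.25 with slide as a fixed block (adjusted p = 0.170) and was not called with a random block (adjusted p = 0.0654). Of 25 B3 domain factors 2 rose and 11 fell (3 and 11 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.0123, adjusted p = 0.290 with an estimated correlation), not called with slide as a fixed block (adjusted p = 0.113). Without E4 replicate 1 the medians were -0.71 for histones, -0.32 for the proteasome and -0.23 for ribosomal proteins. That of histones was -0.75 with slide as a fixed block, and that of ribosomal proteins -0.28 under quantile normalization. After normexp B3 factors had -0.28 and DNA replication -0.19 (-0.22 with scaling on probes measured everywhere).

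Photosynthetic markers moved the other way: 29 of 68 rose, 5 fell and 34 did not pass (37 and 5 adjusted over the list alone), with a median of 1.21 (adjusted p = 2.88e-07, adjusted p = 0.263 with an estimated correlation), which was 0.43 after normexp, 0.59 under quantile normalization and 0.62 with slide as a fixed block. A photosystem II 10 kDa polypeptide (Os08g0200300) rose by 3.11 ± 0.37 (adjusted p = 4.65e-05), measured on 2 of 3 E3 arrays. Of 11 gibberellin genes 6 rose and 5 did not pass (6 and 1 adjusted over the list alone), with a median of 1.27 (adjusted p = 0.0378, adjusted p = 0.401 with an estimated correlation). Of 54 starch and sucrose genes 15 rose, 3 fell and 36 did not pass (19 and 3 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.0414, adjusted p = 0.263 with an estimated correlation). A starch synthase (Os06g0229800) rose at least 5.01-fold from below background (adjusted p = 0.000856). The gibberellin shift was not called without E3 replicate 1 (adjusted p = 0.0505) or E4 replicate 1 (0.0658). Nor was the starch shift called without E1 replicate 1 (adjusted p = 0.0526), E3 replicate 1 (0.0639) or E4 replicate 2 (0.0994). After normexp neither passed (adjusted p = 0.0981 and 0.148). The gibberellin median was 0.59 there, 0.76 under quantile normalization (adjusted p = 0.0594) and 0.52 with slide as a fixed block, and the shift was not called with scaling on probes measured everywhere (adjusted p = 0.0546).

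From E3 to E4 5498 genes changed, 3010 higher and 2488 lower. Among the 18176 genes measured in both stages 4061 changed, 1883 higher and 2178 lower. The share of higher calls, 54.7%, was 41.8% under quantile normalization and 67.9% when arrays were scaled on probes measured everywhere, which moved the median of all genes by 0.13. In the fit with slide as a fixed block 183 genes passed, among them 8 of the 27 genes named here: the gibberellin MYB factor, ANT, the thaumatin gene, arginine decarboxylase, the exostosin gene, Os09g0498500, Os03g0663900 and the glutathione S-transferase. Changes in that fit were 5.55 for the thaumatin gene, 6.11 for the pectin methylesterase inhibitor gene, 6.31 for arginine decarboxylase and -6.20 for the glutathione S-transferase. They were -1.58 for the small heat shock protein (adjusted p = 0.685), -0.31 for MET1-2, -0.46 for MSP1, -0.83 for CMT3A and -1.05 for MET1-1. The count was 3360, 3363 and 3589 without E3 replicate 1, 2 and 3, and 3181 and 3119 without E4 replicate 1 and 3, and it was 6575 without E4 replicate 2. Without E4 replicate 1, MET1-2 (adjusted p = 0.143), PAIR3 (adjusted p = 0.144), CMT3A (adjusted p = 0.0602), histone H3 (adjusted p = 0.0552) and histone H2A (adjusted p = 0.0546, a change of -1.27) no longer passed.

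From E4 to E5, as gametophyte nuclei divide, 9 genes named by the rule fell in the ovule. A glycoside hydrolase family 5 gene (Os10g0370500) fell at least 15.2-fold to below background (adjusted p = 0.00742), and a protein kinase (Os05g0545400) at least 3.95-fold (adjusted p = 0.0430), with a change of 0.07 after the normexp correction. A SHAQKYF-class MYB factor (Os04g0566600) fell by 3.23 ± 0.55 (n = 3 arrays per stage, adjusted p = 0.0430), a bHLH factor (Os01g0566800) fell by 2.78 ± 0.40 (adjusted p = 0.0129) and a pectinesterase-like gene (Os07g0119400) by 1.86 ± 0.26 (adjusted p = 0.0110), each measured on 2 of 3 E5 arrays. A calcium-binding protein (Os01g0135700) fell by 2.61 ± 0.34 (adjusted p = 0.0110), a ZF-HD homeobox gene (Os09g0466400) by 2.22 ± 0.34 (adjusted p = 0.0198) and a NUDIX hydrolase (Os02g0734300) by 1.96 ± 0.27 (adjusted p = 0.0110). A caleosin (Os03g0222600), an oil body protein, fell by 1.28 ± 0.21 (adjusted p = 0.0280).

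By list, no histone, proteasome or ribosomal protein gene passed, over all genes or adjusted over the list alone. Their medians were -0.42 for histones (adjusted p = 8.40e-06), -0.15 for the proteasome (adjusted p = 0.0123) and -0.24 for ribosomal proteins (adjusted p = 1.24e-11), with adjusted p = 0.720, 0.769 and 0.702 with an estimated correlation. These shifts differed between slides, at 0.18 on slide 1 and -1.23 on slide 2 for histones, 0.20 and -0.38 for the proteasome and 0.06 and -0.45 for ribosomal proteins. Without E4 replicate 2 the medians were 0.07 for histones (adjusted p = 0.548), 0.06 for the proteasome (adjusted p = 0.0677) and -0.05 for ribosomal proteins (adjusted p = 0.191). Without both E4 replicate 2 and E5 replicate 3 they were -0.06 (adjusted p = 0.462), 0.13 (adjusted p = 0.000666, a call opposite to the first) and -0.04 (adjusted p = 0.298). Without E4 replicate 1 they were -0.84, -0.32 and -0.45, and under quantile normalization -0.26, -0.08 and -0.12. The proteasome shift was also not called without E5 replicate 3 (-0.07, adjusted p = 0.276), on scan 1 alone (-0.07, adjusted p = 0.374) or with slide as a fixed block (-0.08, adjusted p = 0.166). In the fit with that block, at the preset correlation, DNA replication genes (median -0.38, adjusted p = 9.34e-06), heat shock and chaperone genes (median -0.13, adjusted p = 0.00391) and photosynthetic markers (median 0.37, adjusted p = 0.000500) shifted, which they did not without it. Of 25 B3 domain factors none passed, with a median of 0.22 (adjusted p = 0.0314, adjusted p = 0.349 with an estimated correlation). That shift was not called after normexp (adjusted p = 0.213), with slide as a fixed block (adjusted p = 0.170), on scan 1 alone (0.11, adjusted p = 0.108) or without E4 replicate 1 (-0.0043, adjusted p = 0.275), E5 replicate 1 (0.15, adjusted p = 0.110) or E5 replicate 3 (0.11, adjusted p = 0.1).

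From E4 to E5 15 genes changed, 2 higher and 13 lower, and all 5 that changed among the 18168 genes measured in both stages were lower. At an unadjusted p under 0.05 there were 1531 genes. The share of higher calls, 13.3%, was 0% after normexp and 26.7% without E4 replicate 2 and E5 replicate 3. With slide as a fixed block limma called 0 genes (the 9 named genes had changes from -4.81 to -1.23, against -4.63 to -1.28 without the block, and adjusted p from 0.370 to 0.401), and fitted on the arrays of these stages alone it also called 0. The count was 6 without E4 replicate 3 or E5 replicate 1, 25 without E4 replicate 2, 29 without E4 replicate 1 or E5 replicate 2 and 37 without E1 replicate 1. The MYB factor and the protein kinase each lost their call when any 1 of 15 arrays was left out (adjusted p up to 0.118, without E4 replicate 2, and 0.147, without E5 replicate 1). So did the caleosin for any 1 of 5 arrays (up to 0.101, without E5 replicate 3), the ZF-HD gene for any 1 of 3 (up to 0.0643, without E5 replicate 3) and the bHLH factor without E5 replicate 1 (0.0603).

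The comparison of E5 to E6 ends in the mature ovule. Of 16 DNA methylation and polycomb genes 4 fell: MET1-1 (Os03g0798300) by 1.32 ± 0.36 (SE, n = 3 and 4 arrays, adjusted p = 0.0246), CMT3A (Os10g0104900) by 1.30 ± 0.38 (adjusted p = 0.0338), MET1-2 (Os07g0182900) by 1.22 ± 0.31 (adjusted p = 0.0176), and the DEMETER glycosylase gene (Os05g0445900), of a family that removes methylated cytosine, by 0.81 ± 0.17 (adjusted p = 0.00603). Of 32 DNA replication genes 4 fell, among them ribonucleotide reductase (Os02g0804900), which makes DNA precursors (-0.93 ± 0.19, adjusted p = 0.00556), the sliding clamp PCNA (Os02g0805200, -0.98 ± 0.24, adjusted p = 0.0148) and the helicase subunit MCM2 (Os11g0484300, -0.74 ± 0.18, adjusted p = 0.0146). Among genes of meiosis and recombination MEL1 (Os03g0800200) fell by 1.47 ± 0.31 (adjusted p = 0.00624), ZEP1 (Os04g0452500), of the synaptonemal complex, by 1.30 ± 0.34 (adjusted p = 0.0211), PAIR3 (Os10g0405500) by 1.11 ± 0.30 (adjusted p = 0.0222) and MSP1 (Os01g0917500) by 1.05 ± 0.17 (adjusted p = 0.00116). RAD51A2 (Os12g0497300) fell by 1.06 ± 0.22 (adjusted p = 0.00480). OsMADS5 (Os06g0162800) fell by 2.74 ± 0.29 (adjusted p = 5.70e-05), and the homeobox gene OSH1 (Os03g0727000), which maintains meristems, by 2.12 ± 0.60 (adjusted p = 0.0303).

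The thaumatin gene Os12g0568900, which rose from E3 to E4, fell by 7.48 ± 0.74 (adjusted p = 3.54e-05) and was measured on 3 of 4 E6 arrays. Another thaumatin-like gene (Os07g0419300) fell by 5.50 ± 1.06 (adjusted p = 0.00332) and the senescence-associated gene SAG102 (Os04g0586200) by 4.59 ± 0.72 (adjusted p = 0.000865). An L-asparaginase (Os04g0650700), which releases nitrogen from asparagine, fell by 3.76 ± 0.65 (adjusted p = 0.00158). A bZIP factor (Os12g0152900) fell by 3.80 ± 0.31 (adjusted p = 1.49e-05), measured on 1 of 4 E6 arrays. Among the rises, MYB8 (Os01g0637800) rose at least 32.5-fold (adjusted p = 5.70e-05) and monosaccharide transporter 3 (Os09g0268300) at least 16.8-fold (adjusted p = 0.000162). A Bowman-Birk inhibitor (Os01g0124100) rose at least 14-fold (adjusted p = 3.34e-05). All 3 were below background in E5. A receptor extracellular region gene (Os02g0580900) rose by 5.88 ± 0.57 (adjusted p = 3.31e-05), measured on 2 of 3 E5 arrays, and an arabinofuranosidase (Os11g0673200), a cell wall enzyme, by 4.11 ± 0.38 (adjusted p = 2.79e-05). A lipid transfer protein (Os11g0116000) rose (adjusted p = 0.000300), without a bound, since only another of its probes was above background in E5. Of the 10 largest rises and the 10 largest falls, 6 and 2 were below background in the lower stage.

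Histone genes fell in 20 of 50 cases with none rising and 30 not passing (0 and 27 adjusted over the list alone), with a median of -1.03 (adjusted p = 1.36e-11, adjusted p = 0.657 with an estimated correlation). A histone H2A gene (Os08g0427700) fell by 2.18 ± 0.41 (adjusted p = 0.00287) and a histone H3 gene (Os06g0160100) by 2.09 ± 0.40 (adjusted p = 0.00303). Of 56 mitotic cyclin and spindle genes 19 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -0.52 (adjusted p = 6.10e-07, adjusted p = 0.423 with an estimated correlation). The kinesin Os03g0773600 fell by 1.60 ± 0.29 (adjusted p = 0.00247). The gene of that list that rose, by 2.04 ± 0.29 (Os03g0220100, adjusted p = 0.000388), is described as a fatty acid condensing enzyme of wax synthesis, not a spindle gene. DNA replication genes fell in 4 of 32 cases (11 adjusted over the list alone), with a median of -0.58 (adjusted p = 0.00128, adjusted p = 0.688 with an estimated correlation). Of 27 meiosis genes 6 fell and 21 did not pass (10 fell and 1 rose adjusted over the list alone), with a median of -0.47 (adjusted p = 0.000984, adjusted p = 0.263 with an estimated correlation). Of 16 DNA methylation and polycomb genes 4 fell (6 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.0306, adjusted p = 0.263 with an estimated correlation). The replication shift, with a median of -0.30, and the methylation shift were not called without E5 replicate 3 (adjusted p = 0.139 and 0.1), nor the methylation shift after normexp (adjusted p = 0.137).

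**Figure D4:**
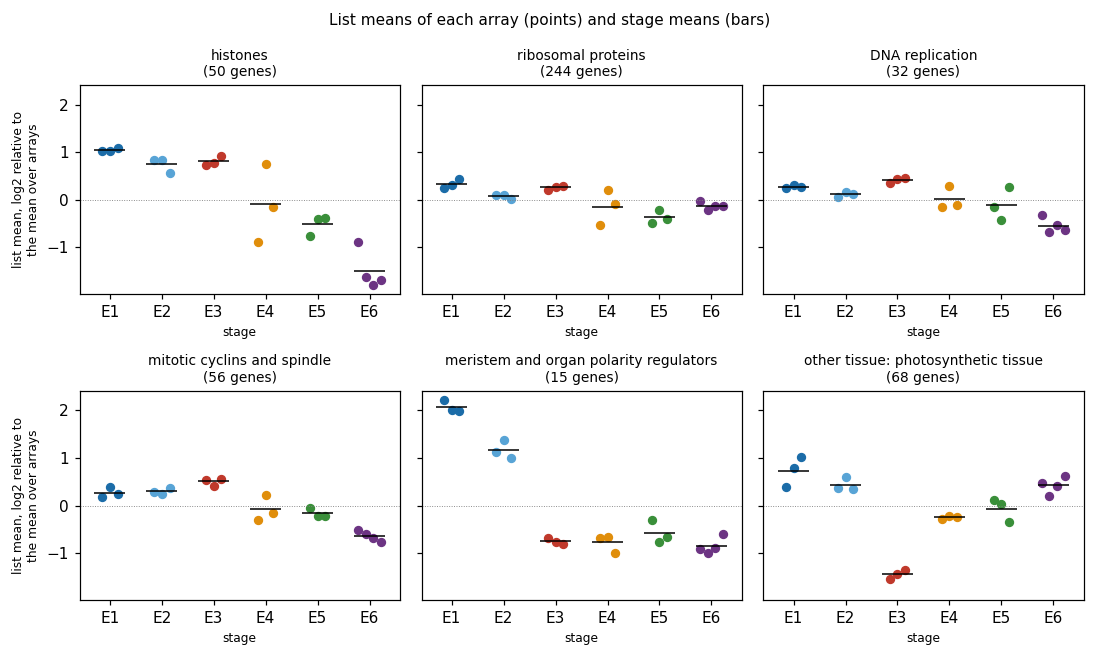
Mean of each list's genes on each array (points, log2 relative to the genes' mean over the 19 arrays) and mean of each stage (bars), for 6 of the fixed lists. Histones were lower in E4 than E3 (median -1.18) and in E6 than E5 (-1.03). Ribosomal protein genes were lower in E5 than E1 (-0.75), but higher after normexp (0.44), whose offset exceeds most E1 signals.

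Ribosomal protein genes rose in 26 of 244 cases with none falling (22 and 0 adjusted over the list alone), with a median of 0.26 (adjusted p = 1.39e-07, adjusted p = 0.720 with an estimated correlation). L38 (Os05g0507200) rose by 1.35 ± 0.42 (adjusted p = 0.0466). Photosynthetic markers rose in 7 of 68 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.00628, adjusted p = 0.559 with an estimated correlation) that turned to -0.11 under normexp. Among them a plastocyanin-like gene (Os08g0482700) rose by 2.61 ± 0.46 (adjusted p = 0.00196) and photosystem I subunit XI (Os12g0420400) by 2.13 ± 0.27 (adjusted p = 0.000172). That shift had an adjusted p of 0.1 without E5 replicate 3 and 0.373 after normexp. Of 75 cysteine-rich secreted peptide genes 17 rose and 2 fell (18 and 2 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.00846, adjusted p = 0.423 with an estimated correlation) that was 0.18 without E5 replicate 1 and turned to -0.06 under normexp (adjusted p = 0.0511). Markers of vascular and lignified tissue rose in 6 of 30 cases and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.304), among them a laccase (Os01g0827300) that rose at least 4.93-fold from below background (adjusted p = 8.99e-05) but changed by -0.14 under normexp. None of 6 pollen markers passed (adjusted p = 0.302, 0 adjusted over the list alone), 1 of 8 tapetum and anther wall markers rose and 2 fell (1 and 3 adjusted over the list alone, adjusted p = 0.420), and none of the 3 egg cell and gamete genes passed (0 adjusted over the list alone).

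From E5 to E6 2658 genes changed, 1222 higher and 1436 lower. Among the 18494 genes measured in both stages 2190 changed, 968 higher and 1222 lower. All E6 arrays are on slide 6, which holds no other stage, so slide, scan and stage cannot be told apart here and no value with slide as a fixed block exists. In the fit with slide as a random block 1411 genes passed, and 9 of the 33 genes named here did not, each of which also lost its call without at least 1 array: MET1-1, CMT3A, MET1-2, PCNA and MCM2 (highest adjusted p without E5 replicate 3: 0.0866, 0.109, 0.0710, 0.0612 and 0.0558), PAIR3, OSH1 and L38 (without E5 replicate 1: 0.0930, 0.101 and 0.228, the last with a change of 0.84) and ZEP1 (without E5 replicate 2: 0.0870). The count was 1616 without E5 replicate 1 and 1723 without E6 replicate 4.

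The comparison of E2 to E4 spans the meiotic divisions, and its first and second replicates share slides. ANT (Os07g0124700) fell by 5.37 ± 0.33 (SE, n = 3 arrays per stage, adjusted p = 9.38e-08) and the auxin response gene IAA18 (Os02g0228900) fell by 5.46 ± 0.48 (adjusted p = 1.75e-06). The gene described as BABY BOOM1 at Os04g0653600 fell by 3.47 ± 0.28 (adjusted p = 9.37e-07). OsMADS34 (Os03g0753100) fell by 4.01 ± 0.33 (adjusted p = 9.37e-07), XRCC3 (Os02g0562100) by 3.59 ± 0.58 (adjusted p = 0.000210) and histone H2B.1 (Os01g0149400) by 3.22 ± 0.32 (adjusted p = 4.70e-06). MSP1 (Os01g0917500) fell by 1.57 ± 0.19 (adjusted p = 1.54e-05). OsMADS17 (Os04g0580700), of the AGL6 group, rose by 3.22 ± 0.44 (adjusted p = 5.30e-05). Below background in E2, the polycomb gene EZ1 (Os03g0307800) rose at least 2.16-fold (adjusted p = 2.30e-05) and a MutS mismatch repair gene (Os10g0509000) at least 1.26-fold (adjusted p = 0.000712), but they changed by -0.63 and -1.27 after normexp.

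Also from below background in E2, the BURP gene Os02g0288600 rose at least 62.2-fold (adjusted p = 3.58e-06), the thaumatin gene Os12g0568900 at least 46.8-fold (adjusted p = 1.25e-05) and a lipid transfer or amylase inhibitor family gene (Os03g0385400) at least 45.7-fold (adjusted p = 9.35e-10). An early nodulin 93 gene (Os06g0142200), below background in E2 too, rose by 9.34 on slide 1 and 0.95 on slide 2. Its means give at least 26.9-fold (adjusted p = 0.00358). A VQ domain gene (Os04g0645200) fell at least 99.8-fold (adjusted p = 1.65e-09) and a serine carboxypeptidase (Os01g0332500) at least 70.9-fold (adjusted p = 7.02e-08), both to below background. Farnesyl diphosphate synthase (Os04g0657100) fell by 8.24 ± 0.79 (adjusted p = 3.74e-06), measured on 1 of 3 E4 arrays, and the NUDIX hydrolase Os11g0531700 by 6.71 ± 0.67 (adjusted p = 5.11e-06), measured on 2 of 3. Of the 5 largest rises and falls, 4 and 3 were below background in the lower stage.

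Of 15 meristem regulators 1 rose, 10 fell and 4 did not pass (1 and 11 adjusted over the list alone), with a median of -1.68 (adjusted p = 0.000462, adjusted p = 0.163 with an estimated correlation), at -1.17 on slide 1 and -1.71 on slide 2. Of 28 MADS-box factors 4 rose and 16 fell (5 and 17 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.0213, adjusted p = 0.559 with an estimated correlation), at -0.83 and -0.55 by slide, although the test pointed up after normexp (adjusted p = 0.443). Histones, with 1 rising and 20 falling of 50 (2 and 23 adjusted over the list alone), had a median of -0.86 (adjusted p = 0.000779, adjusted p = 0.747 with an estimated correlation), but -1.99 on slide 1 against 0.12 on slide 2, and 0.18 after normexp, a call the other way (adjusted p = 0.0215). The proteasome list, with 10 of 54 falling (2 adjusted over the list alone), had a median of -0.29 (adjusted p = 0.0402, adjusted p = 0.797 with an estimated correlation), -0.66 on slide 1, 0.07 on slide 2 and 0.59 after normexp, also a call the other way (adjusted p = 3.49e-09). Its subunit alpha type 2 (Os03g0387100) fell by 1.03 ± 0.24 (adjusted p = 0.00351, and 0.0613 with slide as a fixed block). Of 25 recombination and repair genes 6 rose and 2 fell (6 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0309, adjusted p = 0.559 with an estimated correlation), at 0.42 and 0.36 by slide, that turned to -0.27 after normexp. Seed storage genes fell in 16 of 35 cases and rose in 5 (16 and 5 adjusted over the list alone), with a median of -0.96 (adjusted p = 0.0353, adjusted p = 0.307 with an estimated correlation), at -1.15 and -1.06 by slide.

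From E2 to E4 8366 genes changed, 3679 higher and 4687 lower (2977 measured in E2). Of the 12150 measured in both stages 4960 changed, 2139 higher and 2821 lower. With slide as a fixed block 6875 passed. The share of higher calls, 44.0%, was 59.0% under quantile normalization and 27.5% after normexp, which moved the median of all genes by 0.11 and -0.30. The proteasome shift was not called with slide as a fixed block (adjusted p = 0.103) or a random block (adjusted p = 0.15) or without E4 replicate 1 (adjusted p = 0.416, median -0.15), E4 replicate 3 (0.0952), E1 replicate 1 (0.0756), E2 replicate 2 (0.0728) or E2 replicate 1 (0.0688). Nor was the histone shift without E4 replicate 1 (adjusted p = 0.0675, median -0.40), the recombination shift without E4 replicate 1 (adjusted p = 0.0615) or E2 replicate 1 (adjusted p = 0.0674), or the seed storage shift without E4 replicate 2 (adjusted p = 0.0704) or with slide as a random block (adjusted p = 0.0650). Without E4 replicate 2 the medians were -1.40 for histones and -0.50 for the proteasome, and without E2 replicate 3 or on scan 1 alone 0.43 for recombination. After normexp the meristem (adjusted p = 0.115), seed storage (-1.62, adjusted p = 0.43) and recombination (adjusted p = 0.447) shifts did not pass. Under quantile normalization the seed storage median was -0.22 (adjusted p = 0.147), that of the meristem list -0.95 and that of MADS-box factors -0.41, and the recombination shift did not pass (adjusted p = 0.104).

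The comparison of E1 to E5, whose first and second replicates share slides, runs from before meiosis to the multinuclear gametophyte. ANT (Os07g0124700) fell by 6.48 ± 0.33 (SE, n = 3 arrays per stage, adjusted p = 3.72e-09) and IAA18 (Os02g0228900) fell by 7.21 ± 0.48 (adjusted p = 3.74e-08). MEL1 (Os03g0800200) fell by 4.71 ± 0.33 (adjusted p = 7.35e-08), XRCC3 (Os02g0562100) by 4.35 ± 0.58 (adjusted p = 2.99e-05) and the gene described as BABY BOOM1 at Os03g0770700 fell by 5.62 ± 0.34 (adjusted p = 1.76e-08). The argonaute Os07g0188000 rose by 4.27 ± 0.27 (adjusted p = 2.87e-08). OsMADS29 (Os02g0170300) rose (adjusted p = 2.91e-08), again without a bound. A type 2 metallothionein (Os01g0149800), a metal-binding protein, rose by 5.31 ± 0.32 (adjusted p = 1.81e-08), measured on 1 of 3 E1 arrays.

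All 10 of the largest rises were below background in E1. The BURP gene Os02g0288600 rose at least 111-fold (adjusted p = 7.12e-07), a subtilisin propeptide gene (Os07g0578300) at least 116-fold (adjusted p = 0.00327), an ABC transporter gene (Os01g0836600) at least 52.3-fold (adjusted p = 1.82e-09) and the fatty acyl coenzyme A reductase Os08g0557800 at least 41.5-fold (adjusted p = 4.54e-09). The sucrose transporter Os02g0576600 rose at least 35.5-fold (adjusted p = 3.42e-09). Among the 10 largest falls 6 were below background in E5. A NAM family gene (Os06g0344900), of a family that sets organ boundaries, fell by 8.99 ± 0.41 (adjusted p = 1.21e-09), measured on 1 of 3 E5 arrays. The squamosa promoter binding gene Os07g0505200 fell by 7.73 ± 0.29 (adjusted p = 2.27e-10), a RuBisCO large chain gene (Os02g0166800) by 7.62 ± 0.66 (adjusted p = 6.83e-07), measured on 2 of 3 E5 arrays, and Os03g0663900 at least 113-fold to below background (adjusted p = 4.33e-10). CMT3A (Os10g0104900) fell by 1.67 ± 0.40 (adjusted p = 0.00303) and PCNA (Os02g0805200) by 1.29 ± 0.26 (adjusted p = 0.000822), with a change of 0.12 after normexp.

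Histones fell in 42 of 50 cases with none rising (45 and 1 adjusted over the list alone), with a median of -1.58 (adjusted p = 6.10e-08, adjusted p = 0.720 with an estimated correlation), at -1.92 on slide 1 and -1.50 on slide 2, although the test pointed up after normexp with a median of -0.33. Histone H3.2 (Os12g0415800) fell by 2.98 ± 0.45 (adjusted p = 9.58e-05). Ribosomal protein genes fell in 177 of 244 cases and rose in 10 (188 and 11 adjusted over the list alone), with a median of -0.75 (adjusted p = 6.22e-10, adjusted p = 0.720 with an estimated correlation), at -0.84 and -0.53 by slide. After normexp the shift was called the other way, with a median of 0.44 (adjusted p = 5.37e-11), and under quantile normalization the median was -0.25. L44 (Os07g0450000) fell by 2.92 ± 0.26 (adjusted p = 7.88e-07). Proteasome genes fell in 38 of 54 cases and rose in 1 (42 and 2 adjusted over the list alone), with a median of -0.64 (adjusted p = 5.08e-05, adjusted p = 0.720 with an estimated correlation), at -0.62 and -0.50 by slide. This shift too was called the other way after normexp, with 0.37 (adjusted p = 3.84e-06), and had -0.42 under quantile normalization. Of 15 meristem regulators 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -2.14 (adjusted p = 0.000450, adjusted p = 0.163 with an estimated correlation), at -2.50 and -2.15 by slide. Of 72 auxin genes 36 fell and 10 rose (38 and 10 adjusted over the list alone), with a median of -0.78 (adjusted p = 0.0185, adjusted p = 0.307 with an estimated correlation), at -0.76 and -0.66 by slide, -0.18 under quantile normalization and -1.43 after normexp. Seed storage genes fell in 20 of 35 cases and rose in 5 (21 and 5 adjusted over the list alone), with a median of -1.52 (adjusted p = 0.0330, adjusted p = 0.307 with an estimated correlation), at -0.81 and -1.60 by slide, that turned to 0.02 under quantile normalization. That shift was not called with slide as a fixed block (adjusted p = 0.0530) or without E5 replicate 3 (0.0506), nor under quantile normalization (adjusted p = 0.154). After normexp the seed storage (adjusted p = 0.402), meristem (adjusted p = 0.115), auxin (adjusted p = 0.268) and histone (adjusted p = 0.402) shifts did not pass.

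Other lists went both ways without a shift that passed. Of 56 mitotic cyclin and spindle genes 11 rose and 25 fell (11 and 26 adjusted over the list alone, adjusted p = 0.291). The kinesin Os03g0773600 fell by 3.65 ± 0.31 (adjusted p = 5.89e-07). Of 92 cell wall genes 15 rose and 42 fell (16 and 44 adjusted over the list alone, adjusted p = 0.0691), and the cytokinin, heat shock, metallothionein and small RNA lists did not shift either (adjusted p = 0.116, 0.761, 0.6 and 0.599). Of 161 protease genes 42 rose and 53 fell (42 and 55 adjusted over the list alone), where the median of -0.06 and the mean of -0.47 differ in sign from the test (adjusted p = 0.996).

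From E1 to E5 11124 genes changed, 4702 higher and 6422 lower (3296 measured in E1). Among the 9460 genes measured in both stages 4887 changed, 1763 higher and 3124 lower. With slide as a fixed block 7793 passed, among them all 22 genes named here. The share of higher calls, 42.3%, was 61.7% under quantile normalization, 53.2% when arrays were scaled on probes measured everywhere and 26.7% after normexp, which moved the median of all genes by 0.13, 0.17 and -0.20. Without both E4 replicate 2 and E5 replicate 3, the arrays that stood apart, the counts were 2585 from E1 to E2, 8714 from E2 to E3, 7464 from E3 to E4, 3394 from E5 to E6, 9244 from E2 to E4, 10027 from E1 to E5 and 17041 among all stages.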

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

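The tests of slide, scan, intensity trend, detection limit and a swap of arrays were chosen after the patterns were seen. The test of mixed tissue and the counts of other splits were chosen before.

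Within the 4 E6 arrays, Dixon's ratio of the gap to the range exceeded its 95% critical value in 5 of 64 groups of values, and chance gives that in about 1 in 20 groups (5%). Monosaccharide transporter 3 (Os09g0268300) had a ratio of 0.842, with replicate 4 apart from the others at -2.27. A histone H3 gene (Os06g0160100) had a ratio of 0.855, with replicate 1 apart at 2.52. Among list means, replicate 4 stood apart for MADS-box factors (0.988), and replicate 1 for pollen markers (0.896) and the proteasome (0.884). No biological explanation was tested for these.

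The largest pattern is the difference of E1 and E2 from all later stages, which goes with dim arrays. Against an intensity trend as the whole cause for the 9285 genes above background on every array without a missing value, 78.9% of their E1 to E5 calls (4014 of 5088) stayed called in the same direction after cyclic loess. For the 6237 called genes not above background on every array of both stages, the detection limit of the dim arrays cannot be told apart from a change in the ovules. With slide as a block on scan 1 alone 4929 genes were called, 4832 of them also called over all 19 arrays in the same direction, but position on the slide follows the stage there, so a batch effect of position cannot be told apart from stage. RNA yield, amplification and the stage itself may each contribute and were not tested.

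The E3 arrays, which lie apart from those of E4 and E5, share slide 5 and scan 3. If slide or scan were the whole cause, E5 replicate 3 on that slide would move along the E3 to E4 difference as the E3 arrays do, but its slope was 0.304 ± 0.009 (SE across genes, which are not independent). A partial effect of the slide may remain, and the stage itself stays open and untested.

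E4 replicate 2 lies toward the E3 arrays, with a slope of 0.396 on the E3 minus E5 difference. Slide 2 as the cause is argued against by E5 replicate 2 on the same slide, whose slope was -0.056. A swap with an E3 array is argued against by the lowest correlation between E3 arrays, 0.988, above the highest between E3 and E4, 0.958. Mixed-in E3 tissue would move genes higher in E3 by a larger share than genes lower in E3, but the shares were 0.366 and 0.473, a ratio of 0.775 (0.651 to 0.952 over resampled genes). An ovule sample at an earlier point of stage E4 may account for it, which was not tested.

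Other splits of the same arrays were counted. For E5 to E6, 1 of 35 splits, the real one, reached 2658 genes (highest other 6). For all stages 1 of 100 reached 16616 (highest other 170). Both argue against chance, not against slide. For the list shifts, 5 of 100 splits reached the 45 of the real one (highest other 48), so chance is not excluded. The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05: the real count and the highest other were 1830 and 320 for E1 to E2, 7836 and 0 for E2 to E3, 5498 and 0 for E3 to E4, 8366 and 8 for E2 to E4, and 11124 and 325 for E1 to E5, each with 1 split reaching the real count. For E4 to E5 3 of the 10 splits reached the real 15, with 188 and 254 genes in the others. The latter joins E4 replicate 1 with E5 replicates 1 and 3, which points to sample structure other than stage.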

How the results depend on the processing

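The tests with scaling on probes measured on all arrays, a common floor, genes measured in both stages, E3 to E6 alone, scan 1 alone, E4 replicate 2 and E5 replicate 3 left out, and cyclic loess were chosen after the data were seen. Counts below are genes changed, and the cause of a difference was not tested unless given.

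With normexp background correction, whose offset of 50 exceeds the 75th percentile signal of every E1 and E2 array, the counts were 30 for E1 to E2, 17858 for E2 to E3, 4 for E4 to E5, 17124 for E2 to E4 and 16995 for E1 to E5. Quantile normalization gave 3255 for E3 to E4. Without the filter on dim probes the counts were 1121 (E1 to E2), 16615 (E2 to E3), 16168 (E2 to E4) and 19585 (E1 to E5). With genes above background on every array, fewer genes tested, they were 834, 3270 and 2840 for the first 3 steps, 4014 for E2 to E4, 5092 for E1 to E5 and 7534 among all stages. A floor at the lowest signal above background gave 1067 for E1 to E2, trend and robust settings 37 for E4 to E5, and array weights 852 for E1 to E2, 14395 for E3 to E4, 1879 for E4 to E5 and 7252 for E5 to E6.

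With slide as a fixed block the counts were 413 (E1 to E2), 1261 (E2 to E3), 183 (E3 to E4), 0 (E4 to E5) and 9813 among all stages, and as a random block 3214 (E3 to E4), 37 (E4 to E5) and 1411 (E5 to E6). The replicate numbers were not taken as pairs, although replicates 1 and 2 of E1, E2, E4 and E5 share a slide by number: over 45 same-numbered pairs in different stages, deviations from the stage means correlated from -0.39 to 0.52, 12 over 0.1, and 5 of 18 arrays correlated best with their own number. The replicate block gave 1114 for E1 to E2 and 1501 for E5 to E6. On only the compared groups, with fewer samples, limma gave 0 for E1 to E2, 0 for E4 to E5 and 6243 for E1 to E5. At an unadjusted p under 0.05 these fits had 3367 genes for E1 to E2 and 726 for E4 to E5. For E4 to E5 that number was 1300 with slide as a fixed block and 719 on scan 1 alone, where limma also called 0.

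A common floor gave 4651 (E2 to E3), 3214 (E3 to E4), 39 (E4 to E5) and 7341 (E1 to E5). Genes above background in both stages, fewer genes tested, gave 824 (E1 to E2), 3968 (E2 to E3), 5 (E4 to E5), 5340 (E2 to E4) and 5224 (E1 to E5). Scan 1 alone, with fewer samples, gave 60 (E1 to E2), 0 (E4 to E5), 5148 (E2 to E4) and 6261 (E1 to E5). Without E4 replicate 2 and E5 replicate 3 there were 30 for E4 to E5. Cyclic loess was run over the genes above background on every array without a missing value, 9285 of 9292, so fewer genes were tested. It moved the median of these genes by -0.19 for E2 to E3 and gave 840 (E1 to E2), 2627 (E2 to E3), 2811 (E3 to E4), 3813 (E2 to E4), 4732 (E1 to E5) and 7379 among all stages. With at least 2-fold the counts were 1073, 5213, 3429 and 1470 for E1 to E2, E2 to E3, E3 to E4 and E5 to E6, 5291 for E2 to E4 and 7182 for E1 to E5.

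Leaving out 1 array gave 1020 to 2168 genes for E1 to E2, 6003 to 8364 for E2 to E3, 3119 to 6575 for E3 to E4, 6 to 37 for E4 to E5, 1616 to 3280 for E5 to E6, 6544 to 8903 for E2 to E4, 9345 to 11745 for E1 to E5, 15333 to 17069 among all stages, and 41 to 46 list shifts. From E4 to E5 the histone median ran from -0.84 without E4 replicate 1 to 0.066 without E4 replicate 2, and the proteasome median from -0.32 to 0.062 without the same arrays. List shifts were 0 with an estimated correlation and 84 with fry.

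Some directions turned. With normexp the list medians were 0.18 for histones, -0.59 for MADS-box factors (test up), 0.59 for the proteasome and 0.81 for ribosomal proteins from E2 to E4, and -0.33 for histones (test up), 0.37 for the proteasome, 0.44 for ribosomal proteins and 0.60 for the small RNA pathway from E1 to E5. Of these, histones and the proteasome from E2 to E4 and the proteasome and ribosomal proteins from E1 to E5 were called in both fits, in opposite directions. Genes turned under normexp too: Os01g0859200 (-0.084) and Os03g0307800 (-1.14) from E2 to E3, Os03g0307800 (-0.63) and Os10g0509000 (-1.27) from E2 to E4, Os05g0545400 (0.070) from E4 to E5, Os01g0827300 (-0.14) from E5 to E6 and Os02g0805200 (0.12) from E1 to E5. With slide as a fixed block DNA replication had -0.088 from E2 to E3 and 0.25 from E3 to E4. From E4 to E5 the proteasome had 0.13 without both arrays that stood apart (adjusted p = 0.000666), and protease genes from E1 to E5 (-0.059) turned with fry.

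Of the 149 gene results named, 140 kept direction and call under quantile normalization, 149 with the series table, 113 under normexp (29 lost the call), 67 of 116 with slide as a fixed block and 137 with a random block. Leaving out 1 array kept 2728 of 2831 values. Of 182 list results 149 kept direction and call under normexp (18 lost the call, 7 gained it and 8 turned) and 170 under quantile normalization (9 lost and 3 gained it). Signal over background limits E1 and E2 most: the lowest scaled signal above background was -3.83 to -1.80 there and -7.76 to -5.84 in later stages.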

Other observations

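The tests of these gene groups were chosen after single members had been seen to change, and those members were left out.

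Transposon-related genes had a median change of -1.95 from E2 to E3 (33 genes, 2 higher, 19 lower and 12 not passing, adjusted p = 0.000364, and adjusted p = 0.153 with an estimated correlation). Among the 8 measured in both stages the median was 0.10. Basic helix-loop-helix genes had a median of -0.94 from E1 to E5 (65 genes, 11 higher, 36 lower and 18 not passing, adjusted p = 0.00400, and adjusted p = 0.0527 with an estimated correlation), and -0.93 over the 29 measured in both stages. GDSL lipolytic enzyme genes, tested for a rise, had a median of -0.38 from E1 to E5 (44 genes, 11 higher, 14 lower and 19 not passing, adjusted p = 0.911), and 0.01 over the 9 measured in both stages. No rise of the group was found. A fall of the transposon and helix-loop-helix groups may be followed up as a hypothesis, but neither held with an estimated correlation.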
